A study of Mus musculus with 2 samples.

How the data were processed

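Total RNA of mouse hepatoblast cultures at passage 5 and passage 20 was amplified, labelled with Cy3 and hybridised to 1-colour Agilent mouse arrays, 1 array per passage, per the labels' protocols. Spot intensity values were made with Agilent Feature Extraction 10.7.3.1, per the file headers: the deposited intensity is background-subtracted with a spatial detrend, corrected for multiplicative trends, and set to a surrogate value where it does not exceed noise. The mean spot intensity and the local background intensity before subtraction, also deposited, served an alternative only. Other deposited columns flag, spot by spot, saturation, outliers and signal well above background, per the file headers. The authors also deposited a table of log2 values; its columns had the same sorted values (largest gap 0.000609, median 6.31 in each) and correlated with the log2 scanner signal at r = 0.99987 at passage 5 and 0.99986 at passage 20, so its scale was read as log2 after quantile normalization, while the tool is not given in the sources used here. That table is not centred by gene and has no direction of its own.

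Each array held 43379 spots of 41158 gene probes, with 0 saturated spots. Control spots were left out, as were spots with an outlier flag (73 at passage 5 and 69 at passage 20, dropped on both arrays). Log2 signals were averaged over the spots of a probe, and each array's 75th percentile over gene probes was subtracted (signals of 1085 at passage 5 and 853 at passage 20). A gene took the probe with the highest mean value. Its other probes have a difference only where they were well above background on at least 1 array, and the probe ranges given leave out the rest. Of the probes, 27668 were named by accession through the RefSeq table of GRCm38.p6, 5589 by symbol and 471 by an older symbol; 7446 kept the array's own name and were kept apart as unnamed transcripts. Probe positions are those of the files, in build mm9 per the file headers. This gave 20054 named genes, 8890 of them with several probes. By the probe used, 10749 were well above background on both arrays, 366 at passage 20 only, 683 at passage 5 only and 8256 on neither; 12 of the last had another probe above background, and 17 genes above background on 1 array had another probe above it on the other array.

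A gene above background on 1 array only has a bound: the brighter value against the higher of the dim array's own value and its lowest value among probes well above background (-3.32 log2 at passage 5, -3.17 at passage 20). Such values are written as at least N-fold. A gene counted as different at 2-fold. Counts of genes within 2-fold include those whose bound was below 2-fold, although their true difference may be larger. In the gene lists, a member above background on at least 1 array counts as measured, so bounds are included. With 1 array per passage no p-value, standard error or significance call can be made. The error the files give is that of repeat spots: of 245 probes with 10 spots, 115 were above background in all of them, with a median spot SD of 0.055 log2 at passage 5 and 0.059 at passage 20. This leaves out variation between cultures, RNA preparations and arrays. Among 4300 genes with several measured probes the median SD between probes was 0.19 log2; in 483 some probe differed 2-fold, in 137 of these another had the opposite sign, and in 5 probes differed 2-fold in opposite directions. The 7 external spike-in probes above background had a median difference of -0.13 log2 before scaling and 0.21 after it, against a shift of the 75th percentile of -0.35.

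For 38 gene lists, the median of the measured members' differences was placed among 10000 random lists of the same size, matched on level in 10 bins; below percentile 2.5 or above 97.5 a list was said to stand apart, as a description of these arrays. A constant shift between arrays leaves this percentile nearly as it is. Of 37 lists with at least 5 measured members 15 stood apart. Genes named in the report are the 10 largest differences per direction measured on both arrays, the 5 largest bounds per direction, up to 4 members per list with the largest differences and 22 marker genes fixed in advance; provisional names such as Rik clones were skipped, and some genes that the rule takes are not reported here. The closing section also names genes outside this rule: the markers its tests use and a few genes chosen after their values were seen. The lists, this rule and the main alternatives were set before the data were examined. Alternatives were normexp background correction (offset 50), quantile normalization, median centring, loess, stricter and no filters on dim probes, the mean over probes, the authors' values, flagged spots kept, thresholds of 1.5-fold and 4-fold, 20 bins and list means. Scaling to the spike-ins and the 75th percentile over detected probes were added after seeing the data.

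The steps were tested on simulated data for passage 20 against passage 5 with 200 changed genes drawn from the 10749 genes above background on both real arrays and a spread of 0.15 log2 per array: 100% of 3-fold, 4-fold and 8-fold changes and 4% of 1.5-fold changes were called at 2-fold. Among all named genes with a difference in the simulated arrays, 0 of 11523 unchanged ones were called. The simulated spread leaves out variation between cultures, RNA preparations and experiments, and the real differences had an SD of 0.57 log2. The 0 therefore follows from the chosen spread and gives no rate of false calls for the real arrays. Of 200 unshifted lists 5.5% stood apart. These lists were random draws with independent spread, so this share follows from the percentile limits. It gives no rate of false calls for the real lists, whose members need not be independent. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. No genome sequence was used here.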

Results

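Gene expression was measured in expandable hepatoblasts, mouse liver progenitor cells of strain C57BL/6 grown in a chemically defined medium. The medium held epidermal growth factor (EGF), CHIR99021 (an inhibitor of the kinase GSK3), E-616452 (an inhibitor of the TGF-beta type I receptor), lysophosphatidic acid (LPA) and sphingosine 1-phosphate (S1P). Total RNA of cells at passage 5 and of cells at passage 20 was hybridised to 1 array each, and per the labels the passages came from separate experiments. Passage and experiment therefore cannot be told apart, and every difference below compares 2 arrays and has no replicate check. The labels do not say which array's cells grew on Matrigel and which on laminin, nor whether the passage 20 cells came from a culture like the passage 5 one. Of 41158 gene probes, 18738 (45.5%) were well above background at passage 5 and 18969 (46.1%) at passage 20. Both arrays lay on the same slide and were read in the same scan. Values are log2 signals relative to each array's 75th percentile, and differences are passage 20 minus passage 5. The number of arrays limits the precision; repeat spots give technical error only, with a median of 0.08 log2 for a difference of single spots and a 95th percentile of 0.25.

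The comparison of early with late passage asks how alike the expression profiles of an early and a late culture were; it does not follow 1 culture over time. Most genes were at similar levels: of 11798 named genes well above background on at least 1 array, 10736 (91.0%) were not called 2-fold different. This count includes genes above background on 1 array only whose bound was below 2-fold, and their true difference may be larger. Of the 10749 genes above background on both arrays, 266 were at least 2-fold higher and 428 at least 2-fold lower. The fetal liver gene Afp differed by 0.09 log2, and the liver transcription factors Hnf4a and Foxa2 by -0.21 and -0.11, with the probes of Hnf4a from -0.21 to 0.52. The duct keratin Krt19 was lower by 1.43-fold, while the secreted matrix protein gene Spp1 (osteopontin) was 6.83-fold higher at passage 20. The antimicrobial lectin gene Reg3b was 110-fold lower, and its relative Reg1 at least 218-fold lower. Across the 10749 genes above background on both arrays, Pearson's r was 0.969 and Spearman's rho 0.968; genes are not independent replicates, so no p-value is given.

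At passage 20, 385 genes were at least 2-fold higher and 677 at least 2-fold lower, so that 36.3% of the differing genes were higher. Of these, 119 and 249 were above background on 1 array only and rest on bounds. At 4-fold the counts were 59 and 161. The share of higher genes depended on the scaling: it was 22.9% with loess between arrays (264 higher, 887 lower), and 233 genes were higher and 964 lower when the arrays were scaled to the external spike-in RNA. Spike-in scaling moved the median difference of all genes from 0.08 to -0.13 log2. With no filter on dim probes, a change of filter and not of scaling, the split was even, at 1286 and 1286. That setting lets in the 8256 genes well above background on neither array, and it kept all 385 higher and 677 lower calls.

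**Figure D1:**
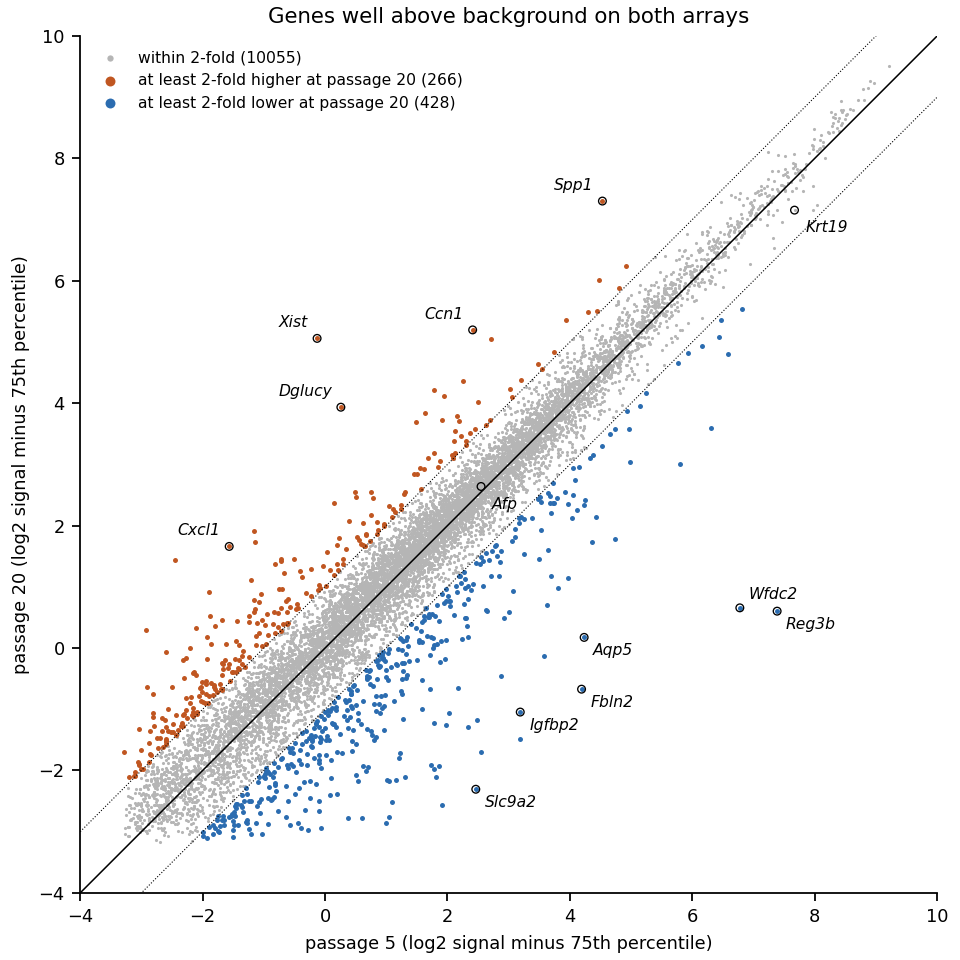
Each point is 1 of the 10749 named genes well above background on both arrays, with its normalized log2 signal at passage 5 (horizontal axis) and passage 20 (vertical axis); the solid line marks equality and the dotted lines 2-fold. Most genes lie between the dotted lines (r = 0.969), with 266 above and 428 below, and Reg3b and Wfdc2 lie far below.

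Among genes measured on both arrays, Xist, the RNA that silences an X chromosome, had the largest excess at passage 20 (36.5-fold, with a bound of 3.74 log2 for its lowest probe). The mitochondrial enzyme gene Dglucy was 12.8-fold (its other probe 2.56 log2) and the neutrophil chemokine gene Cxcl1 9.36-fold higher. Smim22 was 7.40-fold higher, the matricellular gene Ccn1 6.90-fold and Klra4 5.81-fold. The imprinted long RNA Kcnq1ot1 was higher by 2.81 log2. Of genes above background at passage 20 only, Tsix, Mtus2 and Bst1 were at least 17.6-fold, 15.2-fold and 15.2-fold higher, with a bound of 2.38 log2 for the lowest probe of Mtus2. Olfr881 was at least 9.72-fold and the oxytocin receptor gene Oxtr at least 8.70-fold higher. In the other direction, the epithelial secreted protein gene Wfdc2 was 69.5-fold lower, the matrix gene Fbln2 29.1-fold and the sodium-proton exchanger gene Slc9a2 27.3-fold. C2cd4b was 25.4-fold lower, Tmem88 22.1-fold, the insulin-like growth factor binding protein gene Igfbp2 18.8-fold, the water channel gene Aqp5 16.7-fold and Cox6b2 15.3-fold; the matrix gene Smoc1 differed by -4.25 log2. Of genes above background at passage 5 only, Reg3g was at least 55.3-fold lower, Tspan18 at least 22.7-fold, the Y-linked gene Ddx3y at least 21.4-fold and Gpnmb at least 20.6-fold. Some of these values rest on part of a gene's probes, the others being above background on neither array. This holds for Tspan18 (1 of 3 probes used), Kcnq1ot1 (2 of 6) and Slc9a2, Oxtr, Ddx3y and Gpnmb (1 of 2 each). The probe of Reg3b lies at chromosome 6, 78323323 to 78323382, that of Wfdc2 at chromosome 2, 164393935 to 164393994, and that of Spp1 at chromosome 5, 104869788 to 104869847 (mm9).

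Most hepatoblast markers were within 2-fold, but a smaller share than the 91.0% of all detected genes. Of 21 measured members, 15 were within 2-fold, 3 were higher and 3 lower, and the list median of -0.11 log2 lay at percentile 2.94 of random lists matched on level. The list stood apart as lower with normexp (percentile 0.58), but its median was positive with no filter on dim probes (0.10, percentile 35.0) and with the mean over a gene's probes (0.03, percentile 33.1). The fetal glypican gene Gpc3 was at least 9.49-fold lower, the RNA-binding protein gene Lin28b 3.32-fold lower and the adhesion gene Epcam 2.24-fold lower. Only 1 of the 4 probes of Lin28b was above background. The E-cadherin gene Cdh1 was 2.89-fold higher. Lgr5, a Wnt target and stem cell receptor gene, was 2.24-fold higher by its brightest probe, but its probes ranged from -0.73 to 1.16 log2. Dlk1, another fetal liver marker, was not well above background on either array.

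**Figure D2:**
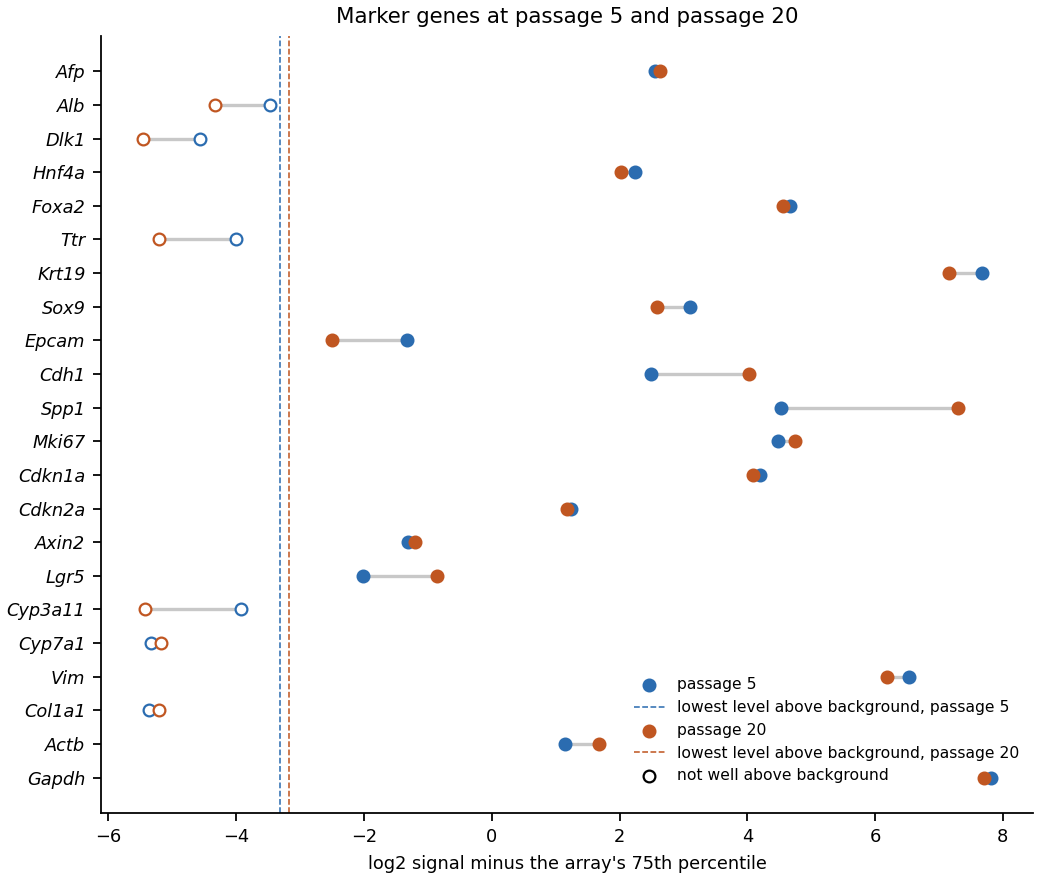
Normalized log2 signal (horizontal axis) of 22 marker genes chosen before the data were examined, with passage 5 in blue and passage 20 in orange; open circles were not well above background, and dashed lines mark each array's lowest level above background. Afp, Hnf4a and Foxa2 nearly coincide, Spp1 lies 2.77 log2 higher at passage 20, and Alb, Dlk1 and Ttr are below background on both arrays.

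Most measured genes of mature hepatocytes were within 2-fold, but a smaller share than the 91.0% of all detected genes. Many were not detected. Of 54 plasma protein genes on the array, 35 were not well above background on either array, among them Alb and Ttr. Of the 19 measured ones, 14 were within 2-fold, 3 were higher and 2 lower, and their median was -0.25 log2 (percentile 0.84). This median did not hold its sign: it became 0.08 with normexp background correction and 0.28 (percentile 96.2) when both arrays had to be above background. Ambp, the alpha-1-microglobulin precursor gene, was 10.6-fold lower and Apoc2 2.17-fold lower, while the fibrinogen gene Fgb was 3.90-fold and the antithrombin gene Serpinc1 2.37-fold higher. Of 25 measured metabolic enzyme genes, 17 were within 2-fold, 6 were lower and 2 higher, with a median of -0.37 log2 (percentile 0.13). With no filter on dim probes this list no longer stood apart (percentile 5.35). That setting lets in the 27 of 52 members well above background on neither array. The tyrosine breakdown gene Fah was 3.83-fold lower and the aldehyde dehydrogenase gene Aldh2 3.72-fold (probes from -1.90 to -0.48 log2), whereas the bile acid conjugating gene Baat was at least 5.20-fold higher. Of 31 measured genes of drug and bile acid metabolism, 22 were within 2-fold, 7 were lower and 2 higher (median -0.28, percentile 0.14). The canalicular exporter gene Abcc2 was 12.6-fold lower, Abcb1a at least 5.69-fold and Cyp4f14 3.11-fold lower, and Cyp1a1 was 3.21-fold higher. Cyp3a11 and Cyp7a1 were not well above background on either array.

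Biliary markers differed in both directions. Of 37 measured members, 26 were within 2-fold, 4 were higher and 7 lower, with a median of -0.01 log2 (percentile 11.4). Spp1 was higher, as given above, and the fibrocystin gene Pkhd1 was at least 3.62-fold higher, with another probe at 0.33 log2. Aqp5 was lower and the claudin gene Cldn7 at least 3.83-fold lower. The progenitor and duct transcription factor gene Sox9 differed by -0.51 log2. Genes of epithelial junctions and keratins had 7 lower and 1 higher of 43 measured (median -0.18, percentile 0.31). Krt20, a keratin of gut epithelium, was 6.21-fold lower, the connexin gene Gjb2 4.01-fold and the protease inhibitor gene Spint1 3.48-fold lower; Cdh1 was the 1 higher member.

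Genes of DNA replication were slightly higher as a group. Of 58 measured S phase genes, only Ccne2, a cyclin of S phase entry, passed 2-fold (2.61-fold higher), but the list median of 0.31 log2 lay at percentile 100 of the random lists. Under spike-in scaling, which lowers all differences alike, this median was 0.09. Rfc3, Gins3 and Ccne1 were 1.88-fold, 1.86-fold and 1.81-fold higher. The 51 mitotic genes had a median of -0.01 log2 (percentile 4.25); the proliferation marker Mki67 differed by 0.28 log2, and the phosphatase gene Cdc25c was 2.31-fold lower (probes from -1.21 to -0.31 log2). The cell cycle inhibitor genes Cdkn1a and Cdkn2a differed by -0.11 and -0.05 log2. Of 34 measured senescence and inhibitor genes, 7 were higher and 8 lower (median 0.00, percentile 15.5). Igfbp2, Igfbp4 (a bound of -3.59 log2) and Igfbp5 (at least 5.05-fold) were lower and Cxcl1 was higher. When both arrays had to be above background, which leaves out such bounds, the list median was 0.29 (percentile 99.8). Of 35 measured p53 targets, 4 were higher, among them Perp (2.29-fold), Ddit4l (2.25-fold, probes from 0.56 log2) and Btg2 (2.12-fold, probes from 0.60 log2), and 1 was lower, the proapoptotic gene Bbc3 (2.24-fold); the median was 0.11 log2 (percentile 65.7).

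As groups, targets of several signalling pathways had a higher median at passage 20, although most members were within 2-fold. Of 27 measured targets of the coactivators YAP and TAZ, 20 were within 2-fold, 6 were higher and 1 lower (median 0.41 log2, percentile 100). Besides Ccn1, Ccn2 was 5.39-fold and the ankyrin repeat gene Ankrd1 5.08-fold higher, while Fjx1 was at least 3.97-fold lower. Of 25 measured NF-kB and inflammation genes, 17 were within 2-fold, 7 were higher and 1 lower (median 0.53, percentile 100). These included Cxcl1, the adhesion molecule gene Icam1 (4.32-fold) and the feedback inhibitor gene Tnfaip3 (3.27-fold), whereas the chemokine gene Ccl7 was 4.57-fold lower (its other probe -1.40 log2). Of 30 measured genes induced by EGF receptor and ERK signalling, 22 were within 2-fold, 7 were higher and 1 lower (median 0.31, percentile 99.9). The early growth response gene Egr1 was 4.17-fold, Myc 3.47-fold and Phlda1 2.67-fold higher, and the cytokine gene Il33 was 2.94-fold lower. These 3 lists kept a positive median under all 12 alternatives, but under spike-in scaling the medians were 0.20 for YAP and TAZ, 0.32 for NF-kB and 0.10 for ERK.

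Targets of TGF-beta and Wnt, and genes of LPA and S1P signalling, which the medium addresses, differed in both directions, as did Notch genes. Of 35 measured TGF-beta targets, 5 were higher and 6 lower (median 0.22, percentile 97.46, just inside the limit). The list stood apart as higher under 5 of 12 alternatives, among them the authors' values (percentile 98.1) and normexp (98.3), but its mean was only 0.03 (percentile 50.9) and its median under spike-in scaling 0.00. Tgfbi was 13.1-fold and Bhlhe40 5.40-fold lower, while Ccn2 and Ankrd1 were higher. Of 25 measured Wnt/beta-catenin targets, 3 were higher and 5 lower (median 0.08, percentile 52.6), and Axin2 differed by 0.12 log2. The largest difference of this list was that of Myc, which is also in the ERK list and was 3.47-fold higher. Nkd1 was at least 3.29-fold lower, Ephb3 2.92-fold and the glutamine synthetase gene Glul 2.74-fold lower, with 1 of the Glul probes at -0.04 log2. Of 13 measured LPA and S1P genes, Lpar6 was 2.38-fold higher, and Plpp2 (2.25-fold) and Enpp2 (2.07-fold), which encode enzymes of these lipids, were lower. Of 17 measured Notch genes, Lfng was 2.16-fold higher and Hey1 2.52-fold lower.

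Genes of other endodermal organs had the lowest list median, -1.21 log2 (percentile 0.00): 10 of 17 measured members were lower and 3 higher. With no filter on dim probes its median was 0.14 (percentile 2.84), and it no longer stood apart. That setting lets in the 40 of 57 members well above background on neither array, so it says little about the 17 measured ones. Besides Reg1, Reg3b and Reg3g, the gut hormone gene Guca2a (guanylin) was 12.3-fold lower. Markers of some other cell types were lower as well. Of 11 measured stellate and fibroblast markers, 4 were lower and 0 higher (median -0.35, percentile 0.94): Fbln2, Dcn (at least 15.9-fold), Col6a1 (at least 4.18-fold) and Col5a1 (at least 3.47-fold). This list no longer stood apart when both arrays had to be above background (median -0.14, percentile 5.18). The fibroblast collagen gene Col1a1 was not well above background on either array, nor was 1 of the 2 probes of Dcn. Of 13 measured mesothelial markers, 3 were lower and 0 higher (median -0.38, percentile 0.28), namely Igfbp5, Upk3b (at least 4.34-fold) and Wt1 (at least 2.02-fold); with the mean over a gene's probes this list lay at percentile 4.66. Few members of the endothelial (7), leukocyte (8) and erythroid (3) lists were measured. Egfl7 was 3.25-fold and Gata2 at least 3.06-fold lower among the endothelial ones; Cd14 was 2.67-fold higher and S100a9 2.06-fold lower among the leukocyte ones; Tfr2 was at least 3.54-fold lower among the erythroid ones. Of 25 measured genes of mesenchymal transition, 2 were higher and 4 lower (median -0.12, percentile 3.58, and 2.37 with both arrays above background); Mmp14 was 3.16-fold higher, Fstl1 3.54-fold, Wnt5a 2.63-fold (1 of its probes at -0.95 log2) and Sparc 2.61-fold lower, and Vim differed by -0.35 log2. Sex-linked transcripts also differed: Xist and Tsix were higher, and the Y-linked genes Ddx3y and Eif2s3y (at least 20.5-fold) were lower at passage 20.

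Housekeeping functions differed little. None of 74 ribosomal protein genes, 59 respiratory chain genes, 26 sterol genes and 27 reference genes was 2-fold different. Their medians were 0.15, 0.17, 0.18 and 0.18 log2, and all 4 became negative under spike-in scaling (-0.06, -0.04, -0.03 and -0.04). Gapdh differed by -0.11 and Actb by 0.54 log2.

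**Figure D3:**
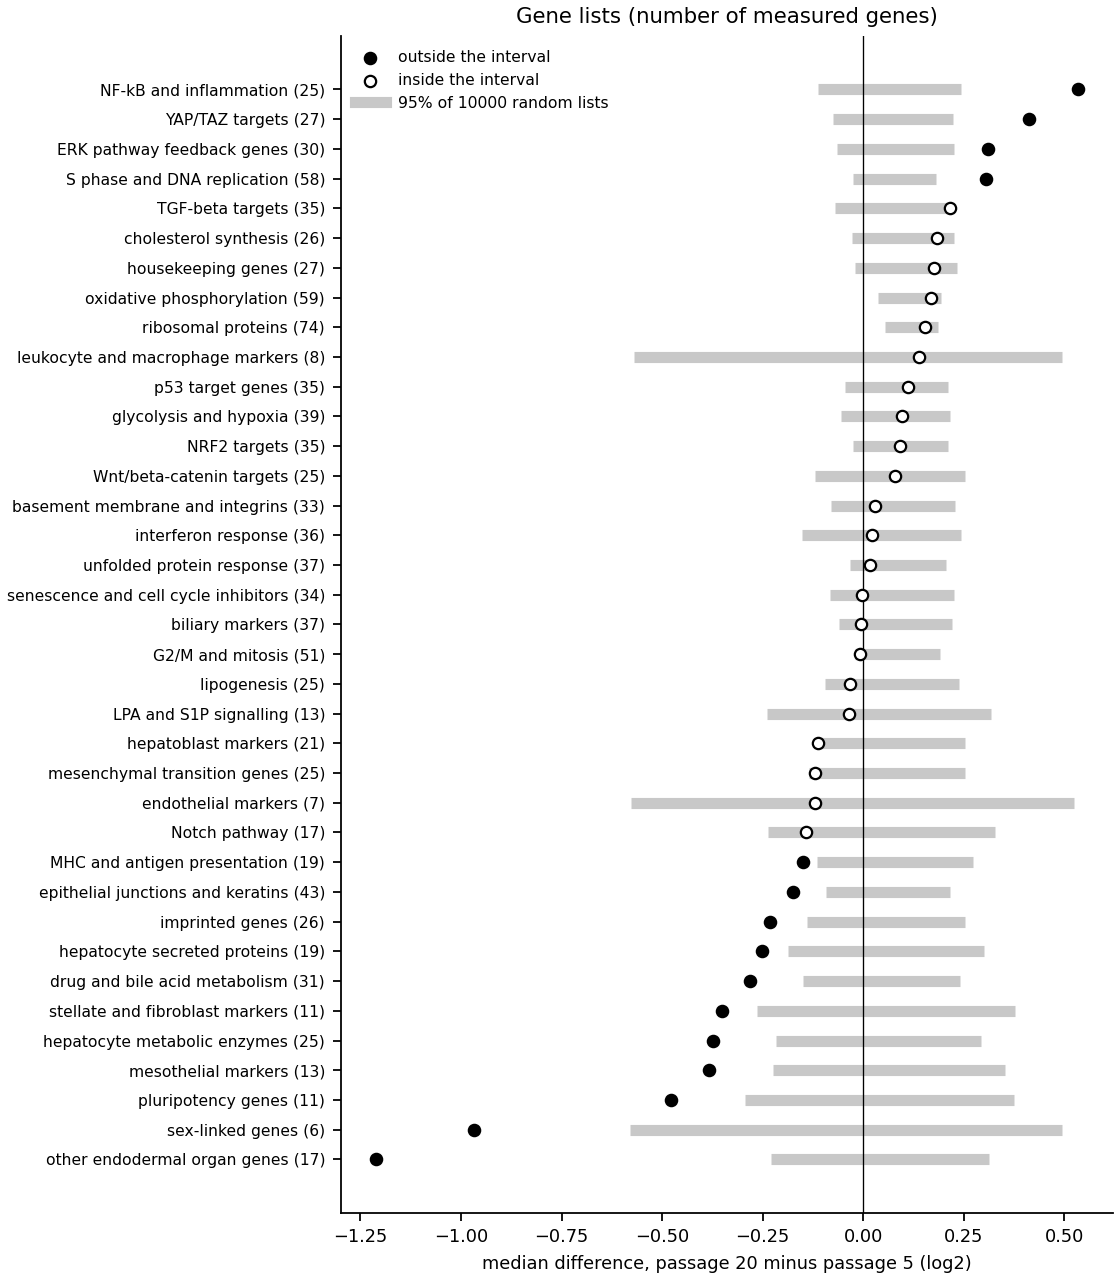
Median difference (log2, passage 20 minus passage 5) of each of 37 gene lists with at least 5 measured members; grey bars span 95% of 10000 random lists matched on level, and filled points lie outside them. NF-kB, YAP/TAZ, ERK and S phase genes lie to the right of their bars, and genes of other endodermal organs lie farthest to the left, at -1.21. Hepatocyte secreted proteins, at -0.25, turn to 0.08 with normexp and to 0.28 when both arrays must be above background. With no filter on dim probes, where the median of all genes is 0.15, the medians of hepatocyte metabolic enzymes, other endodermal organ, stellate, pluripotency and imprinted genes lie between 0.08 and 0.14, below that of all genes. That setting also lets in members well above background on neither array.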

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

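No test in this part was chosen after its result was seen. Transcripts that could not be given a current gene name were kept out of the comparison of passages, and they differed mostly in 1 direction: of 7279 on the array, 1591 were well above background on at least 1 array, 290 were at least 2-fold higher at passage 20 and 48 at least 2-fold lower. They are dim: their median level lay below the 1.02 log2 of named genes. Dim signal alone is argued against, because named genes matched on level were higher in 38.2% of their 2-fold differences (32.3 to 44.9 over 1000 draws), against 85.8% for the unnamed transcripts (exact 95% interval 81.6 to 89.3). Genomic DNA in the passage 20 RNA is argued against by 1070 chemosensory receptor genes, of which 1.776% (19) were above background at passage 20 only and 19 at passage 5 only, against 6.03% of unnamed transcripts (439, exact 95% interval 5.49 to 6.60) at passage 20 only and 151 at passage 5 only. Both exact intervals treat transcripts as independent, which they need not be. They describe these arrays and leave out variation between cultures, RNA preparations and arrays. A larger share of nuclear or unspliced RNA at passage 20, and a difference between the experiments or passages themselves, may account for the pattern and were not tested.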

How the results depend on the processing

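Spike-in scaling and the 75th percentile over detected probes were chosen after seeing the data. The counts of genes at least 2-fold higher at passage 20 (385) and genes at least 2-fold lower at passage 20 (677) became 252 and 398 with normexp, 1286 and 1286 with no filter on dim probes, 1230 and 1388 at 1.5-fold and 59 and 161 at 4-fold; 428 were lower when both arrays had to be above background, and 233 were higher under spike-in scaling. The filters and thresholds change these counts by construction; for normexp the cause was not tested. Of the main calls, 231 higher and 390 lower genes were shared with normexp, and 303 and 676 with the authors' values. The correlation of passage 5 and passage 20 across genes stayed between 0.969 and 0.9762. Among the 8 lead lists, the median of hepatoblast markers stood apart with normexp (-0.184). The median of hepatocyte secreted proteins changed sign with normexp (0.081), with both arrays above background (0.281) and with no filter (0.161), and as a mean (-0.056) the list no longer stood apart. With no filter the median of all genes moved to 0.15, and the medians of metabolic enzymes (0.141, percentile 5.35), stellate and fibroblast markers (0.129, 0.14), other endodermal organ genes (0.144, 2.84), pluripotency genes (0.079, 2.84) and imprinted genes (0.095, 11.1) were positive but below it. Of these only the stellate list still stood apart as lower. This setting lets in the 8256 genes well above background on neither array. Negative controls had a median signal of 24.8 at passage 5 and 21.9 at passage 20, a smaller fall in proportion than that of the 75th percentile (1085 to 853). Scaling therefore leaves such dim signals higher at passage 20, and these sign changes do not show that the measured members changed direction. With both arrays above background, biliary markers (-0.039) and senescence genes (0.294) stood apart. For the list changes other than those with no filter the cause was not tested. The other 88 values of lead lists kept their call; of the other lists' values 325 did, 9 newly stood apart (5 of these TGF-beta targets) and 8 no longer did, besides the 4 that changed sign. For named genes 1629 values stayed on their side of 2-fold, 15 passed it and 28 dropped below it. No named gene past 2-fold changed sign. No paired analysis was possible because each passage has 1 array. Signal over background limits what was seen: 8256 genes have no measured difference.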

Other observations

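In this part, the tests for loss of the Y chromosome and for fibroblasts were chosen after the results were seen. Several gene groups outside the main account differed. Imprinted genes, expressed from 1 parental allele, had 7 lower and 1 higher of 26 measured members (median -0.23 log2, percentile 0.37). Mest was at least 9.44-fold lower, Sgce 7.08-fold and Peg10 at least 3.36-fold lower, and Kcnq1ot1 was the 1 higher member. The median was -0.01 (percentile 13.7) when both arrays had to be above background and 0.09 (percentile 11.1) with no filter on dim probes, so the list did not stand apart under either. Dropping the filter lets in the 21 of 47 members well above background on neither array. Pluripotency genes had 2 lower and 1 higher of 11 (median -0.48, percentile 0.43), but the list did not stand apart with no filter (0.08, percentile 2.84), with the mean over a gene's probes (percentile 4.23) or as a list mean (percentile 4.72). For this list, no filter lets in the 15 of 26 members well above background on neither array. Lefty1 was 3.21-fold lower and Tfcp2l1 2.55-fold higher (1 of its probes at 0.67 log2), while Klf5 had probes from -0.66 to 1.77 log2. Of 37 unfolded protein response genes, 4 were lower: Ddit3 (3.40-fold), Chac1 (3.28-fold), Ppp1r15a (3.17-fold) and Atf3 (2.42-fold), all stress-induced genes downstream of Atf4; the list median was 0.02 (percentile 12.6), while its mean was -0.17 (percentile 1.07).

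Of 39 glycolysis and hypoxia genes, 4 were lower and 1 higher (median 0.10, percentile 55.5), with Ndrg1 5.69-fold, Angptl4 4.84-fold and Adm at least 2.86-fold lower and Car9 at least 3.08-fold higher. Lipogenic genes had 4 lower of 25 (median -0.03, percentile 9.39): Cd36 (at least 3.61-fold), Pparg (2.36-fold), Plin4 (at least 2.31-fold) and Cidec (2.22-fold). Among 33 genes of basement membrane and integrins, 5 were lower and 1 higher (median 0.03, percentile 27.4); Nid1 was 7.13-fold and Itga7 2.74-fold lower and Itgb6 3.42-fold higher. Of 35 NRF2 targets, 2 were higher and 3 lower (median 0.09, percentile 46.8), with Hmox1 2.99-fold lower and Gsta3 2.67-fold higher. Of 36 interferon response genes, 1 was higher and 3 lower (median 0.02, percentile 38.9), and of 19 antigen presentation genes 1, Tap1, was lower (2.22-fold; median -0.15, percentile 1.23). The antigen presentation list did not stand apart with the mean over a gene's probes (percentile 5.52) or as a list mean (percentile 8.99).

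The lower intestinal genes at passage 20 raise a hypothesis, formed after the Reg genes, Guca2a, Cdx2 (-1.21 log2) and Lgals4 (-1.27 log2) had been seen: a wider enterocyte programme may be lower. A separate list of enterocyte genes was written before its values were seen, leaving out genes already seen to be lower. Of 35 on the array 18 were measured, with a median of -0.45 log2 (percentile 0.09; random lists -0.24 to 0.32); 6 were 2-fold lower and 0 higher. The median stood apart under 11 of 12 alternatives and was 0.13 (percentile 5.56) with no filter on dim probes, which lets in all 35. Prap1 (-1.63, a bound), Tm4sf20 (-1.43) and Cdhr2 (-1.41) were lowest, while Lgals2 was 0.86 higher; these were chosen after their values were seen. None of the list is in another fixed list, but Anpep and Dpp4 are also known from hepatocytes and bile ducts. With separate experiments, passage is not shown to be the reason.

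Xist was 36.5-fold higher at passage 20, and Ddx3y, Eif2s3y and Kdm5d were above background at passage 5 only. Loss of the Y chromosome alone is argued against, because the lower of the 2 Xist probes above background on both arrays differed by 5.11 log2. Cells of animals of different sex may account for the pattern: the X-linked genes Kdm6a (0.52), Kdm5c (0.65), Eif2s3x (0.55) and Ddx3x (-0.08), which escape X inactivation, had a median of 0.54 log2 (percentile 98.9, random lists -0.36 to 0.46). This list of 4 genes is smaller than the minimum of 5 used for the other lists, and the alternatives were not run for it. The sex of the animals is not given in the labels, Xist at passage 5 was still 2.74% of its passage 20 level, and a mixed culture stays open. The labels already place the passages in separate experiments.

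Some fibroblast and mesothelial markers were lower at passage 20 (4 of 11 and 3 of 13 measured), and neither list stood apart under every alternative: fibroblast markers lay at percentile 5.18 with both arrays above background and mesothelial markers at 4.66 with the mean over a gene's probes. For fibroblasts or stellate cells, 0 of the 3 abundant collagen genes Col1a1, Col1a2 and Col3a1 were well above background at passage 5. This argues against cells making these collagens there, but not against fibroblasts or stellate cells that do not. Other markers of these cells, Fbln2, Dcn, Col6a1 and Col5a1, were above background at passage 5, while 25 of 36 in that list were so on neither array. Whether the TGF-beta receptor inhibitor of the medium lowered the collagens was not tested. For mesothelial cells, 6 of 11 marker genes were above background at passage 5, but only 2 of these, Upk3b and Wt1, were 2-fold lower, while Msln was 0.48 log2 and Aldh1a2 0.27 log2 higher at passage 20. A small share of mesothelial cells at passage 5 therefore cannot be told apart from expression of these genes by the hepatoblasts, since Msln was bright on both arrays (7.31 and 7.79 log2). A difference between the experiments may also account for it and was not tested.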
